A study of Mus musculus with 57 samples.

How the data were processed

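Single RM1 cells from mouse bone were profiled by full-length RNA-seq, with SMARTer cDNA and Nextera XT libraries and ERCC spike-in RNA, per the labels' protocols. The submitters' processing notes name STAR and RSEM and the builds GRCm38 and mm10, with no versions or roles. Per the series text, the authors normalised the values with BASiCS, a model that uses spike-ins. The deposited values were a signal of this kind, normalised reads per gene and cell that are never negative, in a table of all 57 cells and a table of the 48 cells from the 4 mice with both states. Within each cell 100% of gene values above 0 were whole multiples of 1 step, within a tolerance of 0.01 reads, so whole reads per gene and cell could be recovered. Recovered reads ranged from 945351 to 5306777 per cell. Intervals on shares of cells treat cells as independent, so they cover counting error only and leave out the spread between mice.

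Per the labels, each deposited sample is a single cell, with its state and its mouse. The mouse was the replicate, and the mean of log2(value + 1) over the cells of a mouse and state was the unit, giving 6 dormant and 6 proliferating means over all mice and 4 of each in the mice with both states. Means of mice with 1 cell of a state (mouse 244 for dormant, 288 for proliferating) rest on that cell. Pairing comes from the labels, since cells of both states came from the same mouse. The correlation of the deviations of the paired means was 0.337, 0.164, −0.01 and −0.01 in mice 369, 452, 360 and 1185. The highest correlation between any pair of cells was 0.891, so no pair of cells looked like 1 library.

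Genes above 0 in at least 6 cells were tested, 11843 over all mice and 11579 within mice. The tests were limma (3.58.1) with trend and robust moderation, without a block over all mice and with the mouse as a fixed block within mice. Differences are dormant minus proliferating on the log2(value + 1) scale, which understates changes of low genes, with Benjamini-Hochberg adjustment at 0.05. Cells at 0 enter the means, so a difference also reflects how many cells had the gene above 0. It can then be large and is not a fold change of the level within cells. Gene lists, 40 in number, were written before the data were examined, as were the tests, most of the alternative settings and the rule for named genes. The 36 lists with at least 3 genes tested over all mice, and the 34 within mice, entered limma's camera with a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. List scores and genes detected, 37 measures, were compared by a two-sided exact permutation test that swapped states within the 4 shared mice and permuted them among the other 4, 96 arrangements in all. Because no gene passed, the rule for named genes took the 10 higher and 10 lower genes with the smallest unadjusted p that went the same way in each of the 4 shared mice. It also took up to 4 members per described list with the smallest p, and a fixed set of label, interferon, cell cycle and identity genes, not all of which are reported here.

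edgeR (4.0.16) and DESeq2 (1.42.0) were run on recovered reads summed per mouse and state as alternatives, because normalised values do not suit a count model as the leading test. Other alternatives changed the pseudocount, the filter on low values, the averaging, the weights, the scaling, the cells kept and the mice kept. Cells with eCFP under 100 were called low in the label, a threshold set after the values were seen, as was the number of 37 detected spike-ins that parted cells with fewer from cells with more. The set of leukocyte-rich cells, with at least 5 of 18 pan-leukocyte genes above 0, was planned. Spike-in features were left out of all tests. The labels' protocols say that libraries were made in batches of one state each, so batch and state cannot be told apart, and the batch of each cell was not used here.

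The scripts were tested on simulated data. Whole cells were redrawn with replacement from all cells, whatever their mouse or state, and only the numbers of cells per mouse and state followed the real design. In each dataset 200 genes were changed 4-fold or 16-fold, in 20 datasets for limma and 5 for the count tools. The simulated data thus hold no differences between mice and no gathering of leukocyte-rich cells in some mice, so the rates given may differ from those in the real data. limma called on average 0.2 unchanged genes per dataset over all mice, edgeR 0 and DESeq2 15. edgeR recovered 8.6% and 26.4% of genes changed 4-fold and 16-fold over all mice, and DESeq2 23.8% and 53.8%. With no change the preset camera test called on average 9.3 of 36 lists, and camera with an estimated correlation 0. Gene positions come from a GENCODE annotation of GRCm38. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.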

Results

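RM1 cells, a mouse prostate cancer line carrying genes for the cerulean fluorescent protein (eCFP) and firefly luciferase (Luc2), were labelled with the membrane dye PKH26 and injected into the heart of C57BL/6 mice. Single cells were sorted from bone about 16 days later per the series text, and on days 13 to 26 per the labels of the single mice. PKH26 is diluted at each division, so cells that kept the dye were sorted as dormant and cells that had lost it as proliferating. The deposited tables gave full-length single-cell RNA-seq values for 57 cells from 8 mice. There were 28 dormant cells from 6 mice and 29 proliferating cells from 6 mice, and 4 mice gave cells of both states. The series text states 28 dormant and 32 proliferating cells, of which 29 proliferating cells were analysed here. One mouse gave 11 of the dormant cells and another gave 13 of the proliferating cells. Between 945351 and 5306777 reads per cell were recovered from the normalised values. Between 2397 and 10507 genes were above 0 per cell, with medians of 7236 in dormant and 7647 in proliferating cells. The mouse was the replicate throughout, because cells of one mouse are not independent.

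The tumour label was the first check on the sort. In the table of all cells, eCFP was under 100 normalised reads in 6 of 28 dormant cells (21.4%, exact Clopper-Pearson 95% interval 8.30% to 41.0%), which came from 4 of the 6 mice. It was under 100 in 0 of 29 proliferating cells, which allows a share of up to 10.3% by 3 counts of the total (exact Clopper-Pearson upper limit 11.9%). These intervals treat cells as independent and leave out the spread between mice. Over all 57 cells, 51 had eCFP of at least 100 (89.5%), a cutoff set after the values were seen, and all 57 had eCFP or Luc2 above 0. The series text states more than 83% of cells with the markers. Its cutoff and set of cells may differ, so the shares are not directly comparable. The 6 low-label cells held Lyz2, the lysozyme gene of macrophages and granulocytes, at 52145 to 188632 normalised reads, and Krt8, an epithelial keratin, at 0 to 9.40. Between 9 and 18 of 18 pan-leukocyte genes were above 0 in them. Their eCFP was 0 to 87.6, with a median of 2.47. S100a8, a calcium-binding protein gene of neutrophils, reached 378089 and 180886 in 2 of them. At least 5 pan-leukocyte genes were above 0 in 14 of 28 dormant and 7 of 29 proliferating cells, called leukocyte-rich here. The 2 mice 244 and 360 gave only low-label dormant cells, so that 4 mice with dormant cells remained when these cells were left out.

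**Figure D1:**
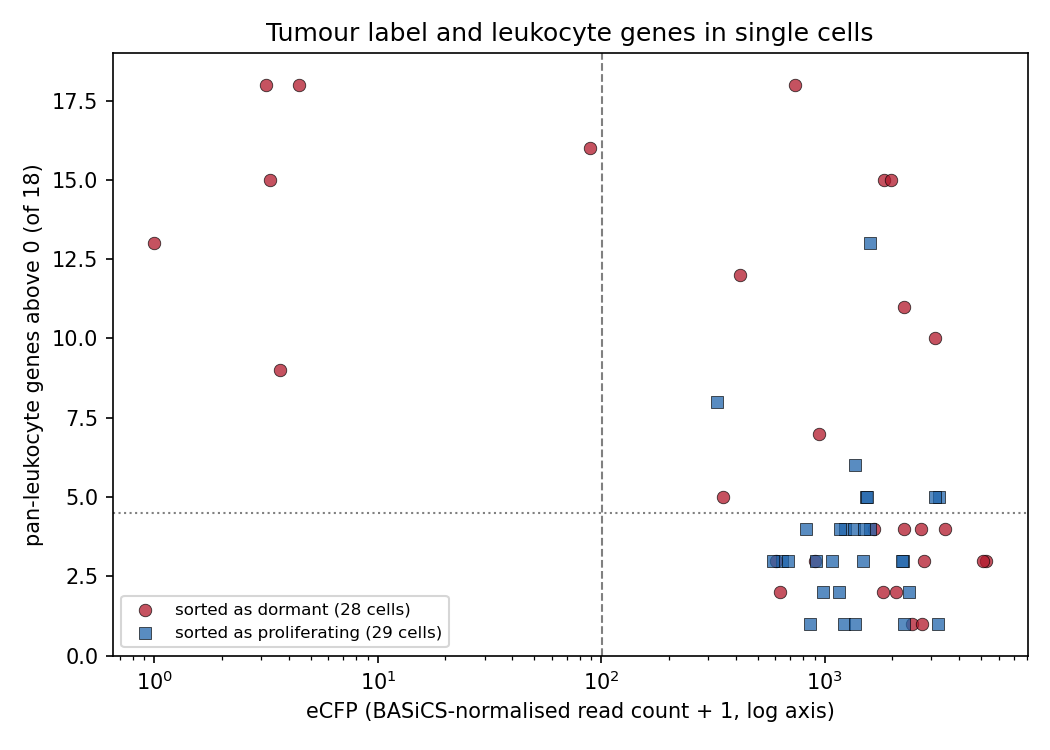
Each point is a single cell, dormant (28 cells, circles) or proliferating (29 cells, squares). The x axis is eCFP in normalised reads plus 1 on a log axis, and the y axis is the number of 18 pan-leukocyte genes above 0. The dashed line marks 100 normalised reads, with 6 dormant and 0 proliferating cells to its left, and cells above the dotted line had at least 5 pan-leukocyte genes above 0.

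The first comparison asked which transcripts differed between dormant and proliferating cells over all mice. Genes of mitosis had lower values and genes of marrow leukocytes higher values in dormant cells. The median log2 difference (dormant minus proliferating, 6 mice each, on the log2(value + 1) scale) was −3.11 over 42 genes of G2/M and mitosis and 4.39 over 17 pan-leukocyte genes. Cenpe, a kinetochore motor, averaged 2.28 ± 2.45 (SD, n = 6) in dormant and 8.15 ± 1.77 (SD, n = 6) in proliferating cells, a difference of −5.87 (SE 1.25). Ccl3, a chemokine gene of activated myeloid cells, averaged 5.84 ± 3.97 (SD, n = 6) and 0.19 ± 0.32 (SD, n = 6), a difference of 5.65 (SE 1.40). Cenpe was above 0 in 14 dormant and 27 proliferating cells, and Ccl3 in 14 and 4. Over the alternative settings Cenpe ranged from −7.66 to −1.66 and Ccl3 from 0.54 to 12.3.

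None of the 11843 genes tested passed limma's test at an adjusted p of 0.05, and the smallest adjusted p was 0.437. At an unadjusted p under 0.05, 389 genes were higher and 737 lower by limma, and the median difference of all genes was −0.35. Without mouse 360 these were 328, 326 and −0.049, and without mouse 244, 483 genes were lower. Of 100 splits of the means between the states, the real one included, 11 gave at least 1126 genes at an unadjusted p under 0.05 by limma. The highest other count was 1915. edgeR on recovered reads called 0 genes, with 665 higher and 118 lower at an unadjusted p under 0.05. DESeq2 on recovered reads called 308, of which 300 were higher in dormant cells. Those 300 included 31 of 88 genes of the marrow lists and 4 of 47 interferon response genes. Without the low-label cells DESeq2 called 16 genes, 15 of them higher. All 15 were among the 300, including the chemokine genes Ccl3 and Ccl4 and the macrophage gene C1qc, and 0 were interferon response genes. The cells kept still included 8 leukocyte-rich dormant cells, and in simulated data DESeq2 called on average 15 unchanged genes per dataset. limma then called 0, with 197 higher and 58 lower at an unadjusted p under 0.05 and a median of 0.10. Without leukocyte-rich cells limma called 0, with 248 higher and 21 lower at an unadjusted p under 0.05 and a median of 0.48. In simulated data of this size limma recovered 2.8% of genes changed 4-fold and 11.25% of those changed 16-fold. The series text states 2410 differentially expressed genes, from the authors' own test, which was not repeated here.

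Since no gene passed, the named genes are given as values. Beside Ccl3, those higher in dormant cells in each of the 4 shared mice with the smallest p were Malat1, a nuclear long non-coding RNA (2.95, SE 0.76), and Ccl4, another chemokine gene (5.04, SE 1.38). Then came C1qc, a complement subunit gene of macrophages (4.70, SE 1.33), Selenop, a selenium carrier (5.45, SE 1.61), and the myeloid surface genes Igsf6 (4.63, SE 1.37) and Ms4a6d (5.10, SE 1.52). Endog, encoding mitochondrial endonuclease G (2.59, SE 0.85), Igf1, a growth factor gene (4.40, SE 1.45), and Akap13, a kinase anchor gene (4.00, SE 1.32), completed them. Without low-label cells Ccl3 differed by 2.61, Ms4a6d by 1.90 and Malat1 by 3.06, and without leukocyte-rich cells Ccl3 differed by 0.54, Malat1 by 3.86, C1qc by −0.012 and Igf1 by −0.077. Beside Cenpe, those lower in dormant cells were Tubb5, a beta tubulin gene (−2.47, SE 0.54), Ccnb1, encoding cyclin B1 (−5.29, SE 1.38), and Nde1, a dynein regulator gene (−3.92, SE 1.03). The actin-binding genes Tpm1 (−2.66, SE 0.67) and Pls3 (−5.14, SE 1.30) were among them, as were Jcad (−5.08, SE 1.17), Tcf12, a transcription factor gene (−3.73, SE 0.98), Chchd4, of mitochondrial import (−4.43, SE 1.18), and the long non-coding RNA Lockd (−4.25, SE 1.13). Without low-label cells Pls3 differed by −1.27, Tubb5 by −1.35, Tpm1 by −1.05 and Cenpe by −4.52, and without leukocyte-rich cells by −0.26, −0.61, −0.046 and −3.06. In GRCm38 coordinates of the reference annotation, Cenpe lies on chromosome 3 from 135212537 to 135273611 and Ccl3 on chromosome 11 from 83647844 to 83649355, both protein-coding.

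The tumour label itself was lower in the dormant means, eCFP by −3.35 (SE 1.25) and Luc2 by −3.89 (SE 1.94), and without the low-label cells these differences were 0.26 and 0.24. Low-label cells were chosen by their eCFP and all were dormant, so the loss of the eCFP difference follows from the choice. Ptprc, the pan-leukocyte surface gene CD45, differed by 4.61 (SE 1.59), and by 1.42 without those cells. Of the keratins, Krt8 differed by −3.92 (SE 1.71) and Krt18 by −0.44 (SE 1.87), and without the low-label cells by 0.16 and 3.57. Vim, an intermediate filament gene of mesenchymal cells, differed by −0.85 (SE 0.40). Mki67 and Top2a, proliferation genes, differed by −2.67 (SE 1.42) and −4.29 (SE 1.33), and the cell cycle inhibitors Cdkn1a and Cdkn1b by −0.58 (SE 0.88) and −0.63 (SE 0.95). Without low-label cells Mki67 differed by −1.21, Top2a by −1.62 and Cdkn1a by 0.24. With all cells none of these passed limma's test, the smallest adjusted p among them being 0.437.

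Of 36 gene lists tested with camera at a preset correlation, 23 passed, 12 higher and 11 lower in dormant cells, and 0 passed with an estimated correlation (smallest adjusted p 0.278). In simulated data with no change the preset test called on average 9.3 of 36 lists and up to 18. G2/M and mitosis was lower, with 41 of 42 members negative and 14 lower adjusted over the list alone, 0 over all genes (adjusted p = 1.05e-15; adjusted p = 0.317 with an estimated correlation). Tacc3 and Ccnb2, spindle and cyclin genes, differed by −4.45 (SE 1.30) and −4.13 (SE 1.28). Without low-label cells the list's median was −1.66 (adjusted p = 2.98e-12), and without leukocyte-rich cells −0.54 (adjusted p = 0.00125). G1/S and DNA replication had 36 of 38 members negative and a median of −1.68 (−1.02 without mouse 360), with 4 lower adjusted over the list alone (adjusted p = 1.79e-06; adjusted p = 0.363 with an estimated correlation). Without leukocyte-rich cells its median was 0.34 and it did not pass (camera adjusted p = 0.401), and Mcm7 differed by −0.18, Ccnd1 by −0.20 and Rrm2 by −0.21. Mcm7, of the replicative helicase, differed by −3.76 (SE 1.00), Ccnd1, encoding cyclin D1, by −3.76 (SE 1.17), and Rrm2, of nucleotide synthesis, by −4.48 (SE 1.44).

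Growth-related lists were also lower in dormant cells. All 74 cytosolic ribosomal protein genes were negative, with a median of −0.84 against −0.35 over all genes and 0 lower adjusted over the list alone (adjusted p = 8.41e-13; adjusted p = 0.402 with an estimated correlation). Rescaling each cell by the median of ratios moved the median of all genes from −0.35 to −0.18 and that of the ribosomal protein list from −0.84 to −0.45 (camera adjusted p = 2.74e-05). Rpl5, a large-subunit gene, differed by −1.49 (SE 0.47). The MYC target list had 30 of 33 members negative and a median of −1.27, with 1 lower adjusted over the list alone, and Eif2s1, a translation initiation factor gene, differed by −2.12 (SE 0.56; adjusted p of the list = 4.64e-08; adjusted p = 0.317 with an estimated correlation). The glycolysis and hypoxia list had a median of −1.27 with 20 of 22 negative, and Gapdh, a glycolytic enzyme gene, differed by −1.02 (SE 0.29; adjusted p of the list = 2.19e-05; adjusted p = 0.317 with an estimated correlation). Without low-label cells the medians were −0.05 for ribosomal proteins, −0.33 for MYC targets and −0.52 for glycolysis and hypoxia, and only the last of these 3 still passed (adjusted p = 0.00021). Without leukocyte-rich cells the MYC target median was 0.14 and the call was lost (camera adjusted p = 0.700).

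Lists of leukocyte and antigen presentation genes were higher in dormant cells. Of 17 pan-leukocyte genes 14 were higher adjusted over the list alone and 0 over all genes, among them Lcp1, a leukocyte actin bundler (6.17, SE 1.74), and Spi1, a myeloid transcription factor gene (4.76, SE 1.47; adjusted p of the list = 5.32e-17; adjusted p = 0.317 with an estimated correlation). The monocyte and macrophage list had a median of 3.98, with 14 of 19 higher adjusted over the list alone, led by Lyz2 at 8.20 (SE 1.97) and Tyrobp, a myeloid adaptor, at 6.71 (SE 1.74; adjusted p of the list = 1.84e-15; adjusted p = 0.278 with an estimated correlation). MHC class II presentation had a median of 3.38, with 6 of 7 higher adjusted over the list alone, and Cd74, the invariant chain, differed by 5.01 (SE 1.51; adjusted p of the list = 1.31e-09; adjusted p = 0.278 with an estimated correlation). Without leukocyte-rich cells the medians of these 3 lists were −0.11, −0.014 and −0.0090, with camera adjusted p of 0.204, 0.289 and 0.700, and Lcp1 differed by −0.067, Lyz2 by 0.24, Tyrobp by −0.024 and Cd74 by 0.19. Leukocyte-rich cells were chosen by genes of the pan-leukocyte list itself. The fall of that list therefore follows from the choice of cells and is no separate evidence. The osteoblast and stromal list, also of marrow, was lower, with 5 of 5 members negative, a median of −1.44 and 1 lower adjusted over the list alone (adjusted p = 0.0129; adjusted p = 0.317 with an estimated correlation). Its median was −0.26 without low-label cells (camera adjusted p = 0.214) and 0.081 without leukocyte-rich cells (adjusted p = 0.700). Erythroid, dendritic, stem and progenitor, and megakaryocyte lists did not pass (camera adjusted p = 0.507, 0.838, 0.672 and 0.453).

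The study asked about interferon signalling inside the tumour cells, which the type I interferon response list addresses. Its median was 1.05 (0.67 without mouse 360), with 37 of 47 members positive and 0 higher adjusted over the list alone or over all genes (adjusted p = 1.25e-08; adjusted p = 0.317 with an estimated correlation). In cells with fewer spike-ins its median was −0.037, although camera still called it higher (adjusted p = 0.00518). Trim30a and Sp100, interferon-induced genes, differed by 3.48 (SE 1.19) and 3.44 (SE 1.34), Samd9l by 3.66 (SE 1.51) and Oas1g by 2.80 (SE 1.19). Without low-label cells these 4 differed by 1.42, 0.71, 0.52 and 0.19, and without leukocyte-rich cells by 1.22, 0.041, −0.24 and −0.11. Irf7, the interferon-amplifying transcription factor gene, differed by 2.51 (SE 1.12) and Ifnar1, a receptor chain gene, by 2.84 (SE 1.42), and neither passed limma's test. Without low-label cells the list's median was 0.19 (camera adjusted p = 0.217), Irf7 differed by 1.07 and Ifnar1 by 2.41. Without leukocyte-rich cells the median was 0.069 while the camera test pointed down (adjusted p = 0.204). Irf7 was above 0 in 4 of 6 low-label cells, with a highest value of 2883. It was above 0 in 7 of 22 labelled dormant cells, highest 67.2, and in 6 of 29 proliferating cells, highest 178. Among labelled cells that were not leukocyte-rich, Irf7 was above 0 in 1 of 14 dormant and 5 of 22 proliferating cells. Among labelled, leukocyte-rich cells it was above 0 in 6 of 8 dormant and 1 of 7 proliferating cells. The 2883 came from the low-label cell nearest the threshold, in mouse 369, with eCFP at 87.6 and Luc2 at 230. Next was 601 in a cell of mouse 360 with eCFP at 2.28.

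**Figure D2:**
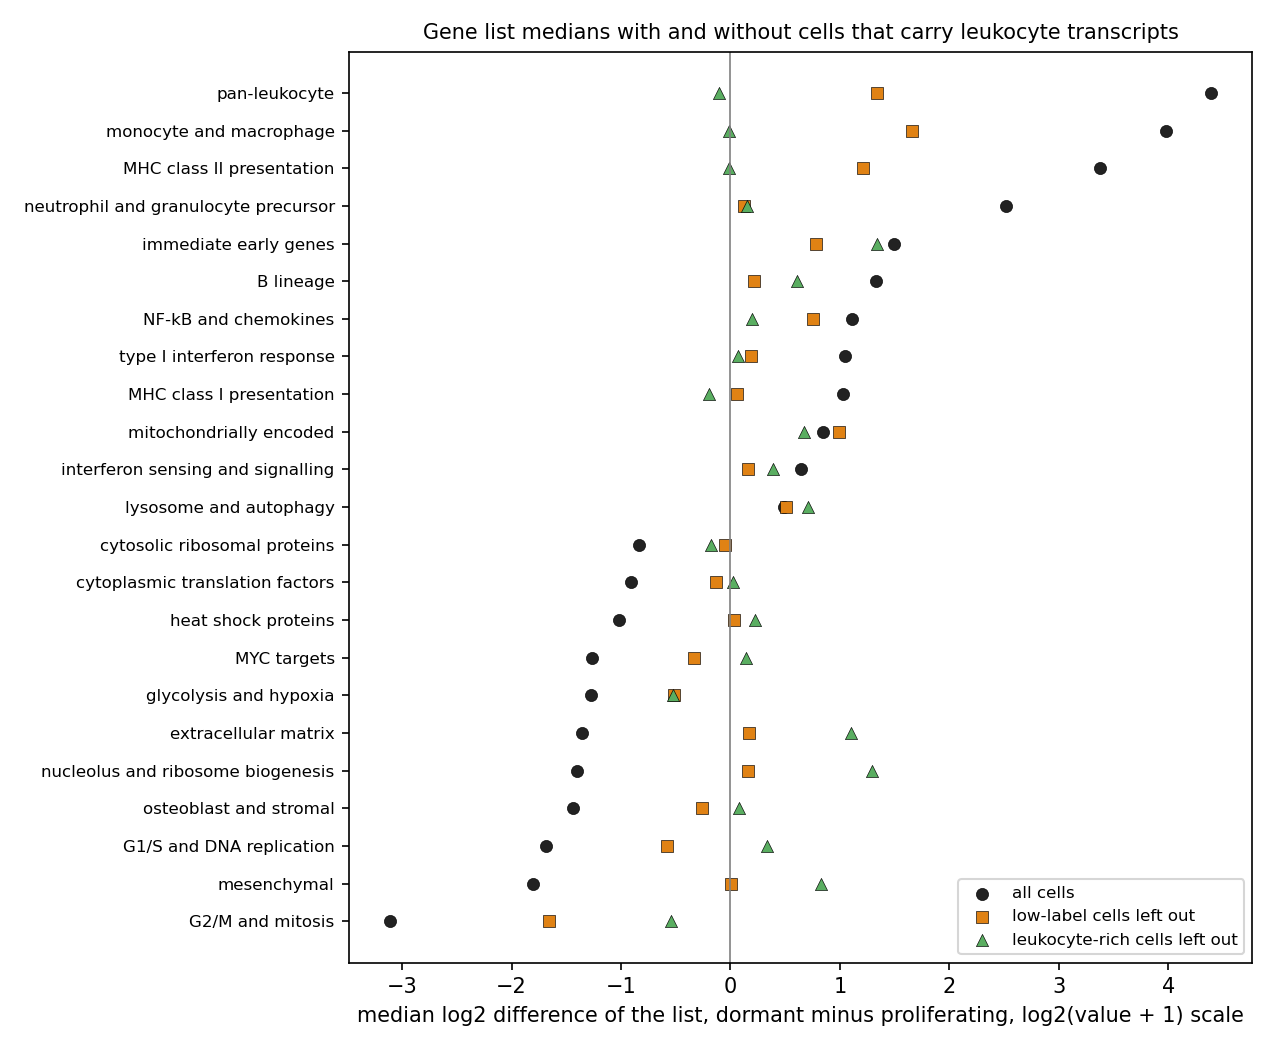
Median log2 difference, dormant minus proliferating on the log2(value + 1) scale, for the 23 lists that passed camera's test at a preset correlation (0 passed with an estimated correlation). Circles use all cells, squares leave out the 6 low-label cells and triangles leave out the leukocyte-rich cells. The pan-leukocyte median goes from 4.39 to 1.34 and −0.11, and the interferon response median from 1.05 to 0.19 and 0.069. Leukocyte-rich cells were chosen by pan-leukocyte genes, so the fall of that list to −0.11 follows from the choice.

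As single values per mouse, the list scores (mean log2 value of a list's genes) were compared by a two-sided exact permutation test, whose smallest p is 0.0208. It swapped states within the 4 shared mice and permuted them among the other 4. The G2/M and mitosis score was 3.46 ± 1.59 (SD, n = 6) in dormant and 6.49 ± 2.28 (SD, n = 6) in proliferating cells, lower in 4 of 4 shared mice (exact permutation p = 0.0625, adjusted p = 0.280 over 37 measures). The interferon response score was 2.99 ± 1.45 (SD, n = 6) and 1.98 ± 0.89 (SD, n = 6), higher in 3 of 4 shared mice (exact permutation p = 0.104, adjusted p = 0.308). The cytoplasmic translation factor score reached the smallest p, with a difference of −0.80 and lower values in 4 of 4 shared mice (exact permutation p = 0.0208, adjusted p = 0.280). None of the 37 measures passed after adjustment by this test, which a single measure at the smallest p could not do, and 2 had an unadjusted p under 0.05, the other being the osteoblast and stromal score (−1.91, exact permutation p = 0.0417). Genes detected per cell differed by −316.5 (exact permutation p = 0.708). Without low-label cells, with 32 arrangements, 0 of 37 measures had an unadjusted p under 0.05 by this test. The cytoplasmic translation factor score was then 9.88 to 10.6 in dormant and 9.62 to 10.8 in proliferating means. The osteoblast and stromal score was then 5.31 to 7.30 in dormant and 5.37 to 7.33 in proliferating means.

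**Figure D3:**
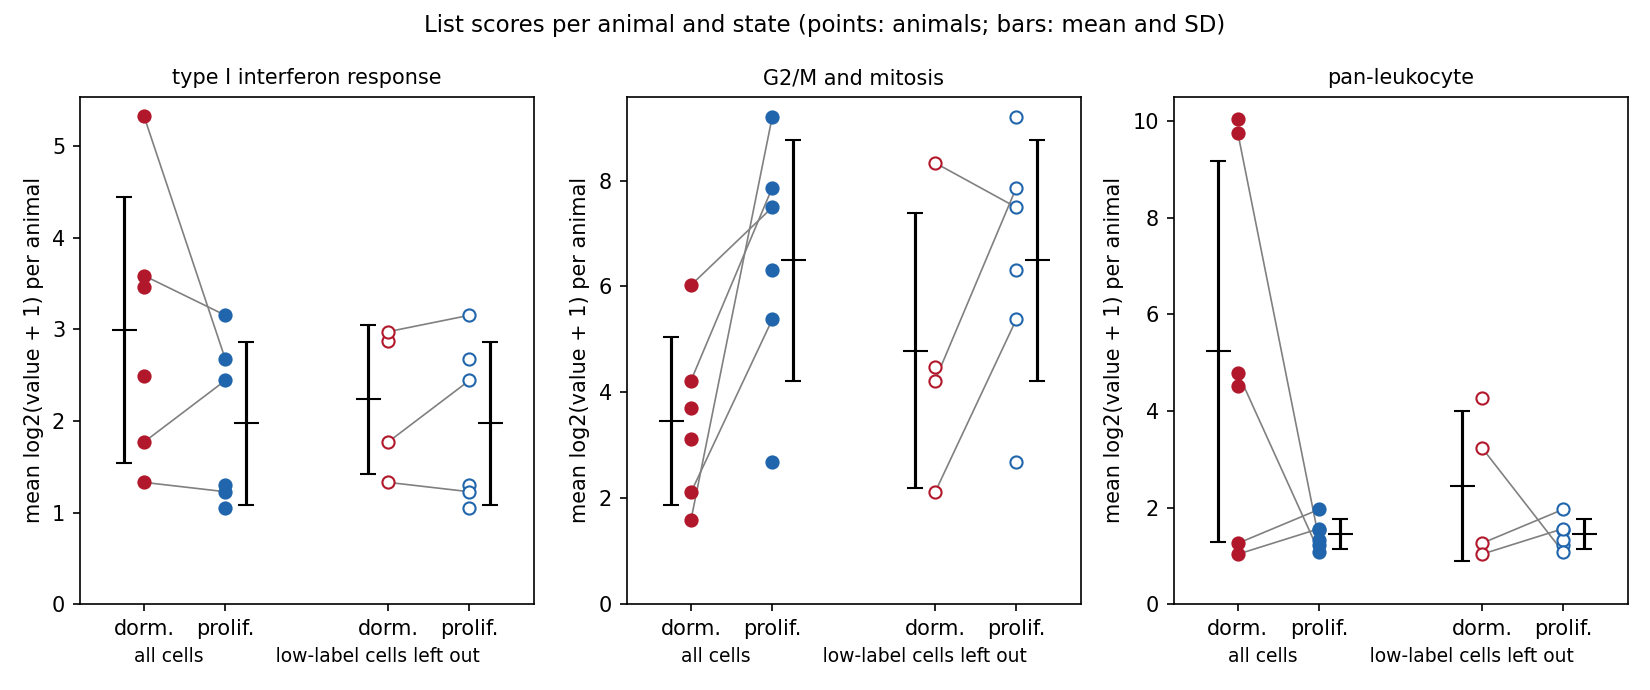
List scores per mouse (mean log2(value + 1) over a list's genes) for interferon response, G2/M and mitosis, and pan-leukocyte genes. Filled points use all cells, open points leave out the 6 low-label cells, lines join the states of one mouse, and bars give mean and SD over mice. With all cells, G2/M and mitosis is lower in the dormant cells of 4 of 4 shared mice, and without low-label cells in 2 of the 3 that remain.

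The second comparison asked the same within the 4 mice that gave both states, with the mouse as a block. Genes of cell division again had lower values in dormant cells. Cenpe averaged 2.75 ± 2.82 (SD, n = 4) in dormant and 9.01 ± 0.84 (SD, n = 4) in proliferating cells, a difference of −6.26 (SE 1.29), and Ccnb1 differed by −5.96 (SE 1.25). The G2/M and mitosis list had 42 of 42 members negative and a median of −4.08, with 37 lower adjusted over the list alone and 0 over all genes (adjusted p = 1.95e-25; adjusted p = 0.475 with an estimated correlation). Its median was −2.07 without low-label cells (adjusted p = 3.5e-18) and −1.75 without leukocyte-rich cells (adjusted p = 2.2e-10). In this comparison both settings also left out mouse 360 altogether, since all its dormant cells were low in the label and leukocyte-rich. They are therefore not separate from leaving out mouse 360.

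None of 11579 genes passed limma's test (smallest adjusted p 0.535), with 120 higher and 950 lower at an unadjusted p under 0.05. edgeR called 0 as well (smallest adjusted p 0.0581), with 151 higher and 99 lower at an unadjusted p under 0.05. In simulated data limma recovered 2.6% of genes changed 4-fold and 12.55% of those changed 16-fold in this comparison. Of 8 splits that swapped states within mice, the real one included, 2 gave at least 1070 genes at an unadjusted p under 0.05 by limma. The highest other count was 1678. The median difference of all genes was −0.72. Without low-label cells it was −0.10, with 128 higher and 234 lower at an unadjusted p under 0.05, and without leukocyte-rich cells −0.027, with 131 higher and 133 lower. Without mouse 360 it was −0.35, with 96 higher and 521 lower, while 196 were higher and 1690 lower without mouse 1185, and 36 higher and 446 lower without mouse 369. Genes lower in each of the 4 mice further included Ccnb2 (−5.29, SE 1.24), Ube2c, a ubiquitin ligase partner of mitotic exit (−5.21, SE 1.24), the spindle genes Mad2l1 (−4.58, SE 1.08) and Hmmr (−5.33, SE 1.28), and Kpna2, a nuclear import gene (−2.76, SE 0.64). Idh3a, of the citric acid cycle (−3.98, SE 0.83), Dkc1, of nucleolar RNA modification (−4.38, SE 0.96), and Tpm1 (−2.92, SE 0.70) were the others. Genes higher in each of the 4 mice were Rasa4, a Ras-inactivating protein gene (3.81, SE 1.17), Ccl3 (4.85, SE 1.53), Malat1 (1.42, SE 0.48), 2010315B03Rik (1.96, SE 0.68) and Clec7a, a myeloid receptor gene (4.10, SE 1.43). Ccl4 (4.38, SE 1.57), the cytokine gene Il1a (2.55, SE 0.92), Endog (2.22, SE 0.80), Rnf25 (2.98, SE 1.09) and Igsf6 (3.46, SE 1.28) completed them. Leaving out low-label cells brought Igsf6 to 0.77, Ccl3 to 1.70, Ccl4 to 1.65, Clec7a to 1.68, Il1a to 1.38 and Rasa4 to 2.55, while Malat1 was at 1.52. The lower genes were then between −4.89 (Cenpe) and −1.49 (Kpna2). Top2a differed by −4.60 (SE 1.23) and Mki67 by −3.89 (SE 1.37). The label differed by −2.56 (SE 1.18) for eCFP and −3.11 (SE 1.47) for Luc2, and Ptprc by 3.59 (SE 1.58). Krt8 differed by −3.43 (SE 1.83), Krt18 by −1.85 (SE 1.51), Vim by −0.71 (SE 0.41), Cdkn1a by −0.81 (SE 0.81) and Cdkn1b by −0.18 (SE 0.79). Without low-label cells the direction turned for eCFP (0.24, SE 0.45), Luc2 (0.13, SE 0.31), Krt8 (0.77, SE 0.38), Krt18 (1.62, SE 0.65) and Cdkn1b (0.76, SE 0.68). For eCFP, by which these cells were chosen, the rise follows from the choice. Ptprc then differed by 0.89, Top2a by −2.09 and Mki67 by −1.99.

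Of 34 lists, 21 passed camera's test within the mice, 11 higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p 0.475). In simulated data with no change the preset test called on average 9.65 lists here and up to 20. Without mouse 360, whose dormant cells were both low in the label, 12 lists passed and the interferon response list did not (median −0.022, camera adjusted p = 0.10). The pan-leukocyte list had a median of 3.29 (0.90 without mouse 360) with 15 of 16 members positive and 0 higher adjusted over the list alone (adjusted p = 1.7e-16; adjusted p = 0.475 with an estimated correlation). Nucleolus and ribosome biogenesis had 24 of 24 members negative and a median of −1.38, with 1 lower adjusted over the list alone (adjusted p = 0.000394; adjusted p = 0.712 with an estimated correlation). Its median was −0.66 without mouse 360, where the call was lost (camera adjusted p = 0.118), and −2.11 without mouse 1185. It was −0.081 without low-label cells (camera adjusted p = 0.981) and 0.052 without leukocyte-rich cells (adjusted p = 0.184). The type I interferon response list had a median of 0.55 (0.93 without mouse 1185) with 28 of 44 positive and 0 higher adjusted over the list alone (adjusted p = 2.54e-08; adjusted p = 0.475 with an estimated correlation). Its median was −0.14 without low-label cells (adjusted p = 0.356) and −0.53 without leukocyte-rich cells, where camera called it lower (adjusted p = 0.0056). Irf7 differed by 2.44 (SE 1.32) and Ifnar1 by 0.66 (SE 1.17), and without low-label cells by 0.29 and 1.16. The unfolded protein response list was called higher although its median was −0.18 and its mean 0.01 (adjusted p = 0.0275; adjusted p = 0.712 with an estimated correlation). The call was lost without mouse 1185, 360 or 452 (medians −0.57, −0.10 and −0.24), and without mouse 369 the median was 0.50.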

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

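Each value here lay far from the other mice of its state by Dixon's gap ratio, a test fixed before the data were examined, or came from data outside the comparisons. The genes checked were those named in the text, so most were chosen after their values were seen. There were 30 such values in 249 groups of mice, 26 of them in proliferating means, and chance gives about 1 in 20. In 10 of the 30 all other mice were at 0, where any value above 0 lies apart and that rate does not apply.

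The dormant mean of mouse 244, a single low-label cell, stood above the other mice in the neutrophil and granulocyte precursor score (13.8, others 1.17 to 3.97), the B lineage score (8.34) and the erythroid score (7.93). In the proliferating mean of mouse 288, also 1 cell, the mitochondrially encoded score was 4.69, the others 9.64 to 10.9, and Tpm1 was 9.55. The dormant mean of mouse 360, with 2 low-label cells, had Nop56, a nucleolar gene, at 5.06, the others 8.13 to 9.20.

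In the proliferating mean of mouse 268, with 2 cells, Cdkn1a was 5.41, Cenpe 4.89, Nop58 5.34, Nop16 5.32 and Shmt2, of serine metabolism, 5.30, all below the other mice. Above them in this mouse were Rasa4 at 7.80, 2010315B03Rik at 1.39 and H2-DMa, of MHC class II loading, at 2.88.

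In the proliferating mean of mouse 1185, Ptprc was 1.49, Sp100 1.37, Spi1 1.47, Tyrobp 3.18, Oasl1 2.13 and Fermt3, a leukocyte integrin activator gene, 0.995, each above the other mice, while none of its list scores lay apart by this ratio. One of its 4 cells had 13 of 18 pan-leukocyte genes above 0 and Lyz2 at 1251. In the proliferating mean of mouse 369, C1qc was 0.325, Igsf6 0.283, Endog 1.31, Il1a 0.506, Trim30a 1.84, H2-Eb1 0.201 and Vav1, a leukocyte signalling gene, 0.141, with 0 in the other 5 mice. Mouse 452 had Ms4a6d at 0.263 with 0 elsewhere and Ccnd1 at 6.40 below the other mice, and mouse 360 had Clec7a at 1.64 with 0 elsewhere.

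Outside the comparisons, features of ERCC Mix1 were above 0 in the 28 dormant cells and features of ERCC Mix2 in the 29 proliferating cells, with no cell carrying both.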

How the results depend on the processing

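Leaving out low-label cells, splitting cells by spike-ins detected, rescaling or leaving out mice for the lists, the unblocked list test within mice and leaving out leukocyte-rich cells for the lists within mice and for the scores were chosen after seeing the data. Over all mice limma's count of 0 held in 25 of 29 alternatives; DESeq2 gave 308 and, without low-label cells, 16, the cell as the unit gave 1 (Cenpe), and cells with more spike-ins only, 2 means per state, gave 25. Within mice the count was 0 in 17 of 17 alternatives, edgeR included, and 0 without the replicate block, so the block changed no gene call. Without any one mouse both counts stayed at 0. Leaving out cells with neither label above 0 removed none, so it tested nothing. Depth was at least 945351 reads per cell, and its effect was not tested by thinning.

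The 23 lists over all mice became 0 with an estimated correlation, 0 by fry, 3 without leukocyte-rich cells and 9 without low-label cells, and 19 to 25 without any one mouse. The 21 lists within mice became 0 with an estimated correlation, 9 without leukocyte-rich cells, 7 without low-label cells, 19 without the replicate block, and 12 to 18 without any one mouse, the 12 without mouse 360. Interferon response (1.05), G2/M and mitosis (−3.11) and pan-leukocyte (4.39) lost their calls over all mice with an estimated correlation (adjusted p = 0.317 each) and by fry (adjusted p = 0.430, 0.176 and 0.196), as did interferon response without low-label cells at 0.19. Within mice they lost them with an estimated correlation, at medians of 0.55, −4.08 and 3.29 (adjusted p = 0.475 each), as did pan-leukocyte without low-label cells at 0.27. Without any one mouse the interferon median ranged from 0.67 to 1.42 over all mice and from −0.022 to 0.93 within mice, the lowest without mouse 360, where the call was lost (adjusted p = 0.10).

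Camera's test turned direction over all mice without leukocyte-rich cells for interferon response (0.069), MHC class I (−0.20) and class II (−0.0090), nucleolus and ribosome biogenesis (1.30), heat shock proteins (0.23), NF-kB and chemokines (0.20), extracellular matrix (1.10), pan-leukocyte (−0.11), neutrophil and granulocyte precursor (0.15) and monocyte and macrophage (−0.014). It also turned for extracellular matrix without low-label cells (0.17) and for the neutrophil list in cells with fewer spike-ins (−0.44). Within mice it turned without leukocyte-rich cells for interferon response (−0.53), interferon sensing (0.045), MHC class I (−0.57) and class II (−0.023), nucleolus (0.052), unfolded protein response (−0.11), NF-kB (−0.034), lysosome and autophagy (−0.43), cytoskeleton and focal adhesion (0.024), pan-leukocyte (−0.048), neutrophil (0.072) and macrophage (−0.052) lists. Without low-label cells within mice it turned for interferon response (−0.14), MHC class I (−0.61), immediate early genes (−0.71), lysosome (−0.23) and neutrophil (−0.19) lists, and for lysosome without mouse 360 (−0.27, range −0.27 to 0.50 without any one mouse). The median alone changed sign, with the test's direction kept, in 18 more values. Over all mice these were G1/S (0.34), MYC targets (0.14), cytoplasmic translation factors (0.027), mesenchymal (0.83) and osteoblast (0.081) lists without leukocyte-rich cells, and nucleolus (0.16), heat shock (0.031) and mesenchymal (0.0075) lists without low-label cells. Others were interferon response (−0.037) and B lineage (−0.015) in cells with fewer spike-ins and the mitochondrially encoded list without mouse 288 (−0.37). Within mice they were unfolded protein response (0.17) and extracellular matrix (0.0082) without low-label cells, interferon response (−0.022), MHC class I (−0.036) and immediate early genes (−0.55) without mouse 360, and unfolded protein response (0.50) and neutrophil (−0.55) without mouse 369. Of the genes named for the smallest p, C1qc (−0.012) and Igf1 (−0.077) turned over all mice without leukocyte-rich cells, and Malat1 (−0.12) within mice by edgeR without low-label cells. Other named genes were recomputed without low-label or leukocyte-rich cells only. Over all mice eCFP (0.87), Luc2 (0.99), Krt8 (0.72), Krt18 (4.33), Cdkn1a (1.52), Nop58 (1.29), Nop16 (0.35), Samd9l, Oas1g, Tyrobp and Lcp1 turned without leukocyte-rich cells. Without low-label cells the first 5 turned, and within mice eCFP, Luc2, Krt8, Krt18, Cdkn1b and Samd9l. These sets of cells are smaller and differ in makeup; otherwise the cause was not tested. Of list values 333 kept the test's direction and call, 2 with a median of the other sign, and 150 kept the direction alone, 16 with such a median; of values of the genes named for p 883 kept both and 16 passed where the leading test had not, mostly by DESeq2.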

Other observations

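Of the tests here, the matched draws for G2/M genes and the counts of other splits were written before their result was seen, and the other tests were chosen after it, including the rules that read them. Several programmes tied to dormancy showed no call between the states. Reported dormancy regulators had a median of −0.08 over 24 genes over all mice (camera adjusted p = 0.341), while the mean was 0.02, and a median of 0.56 without low-label cells (adjusted p = 0.214). Gas6, a ligand of the TAM receptors, differed by 2.83 (SE 1.06) and Bhlhe41, a transcriptional repressor gene, by 1.95 (SE 0.94). Without low-label cells these differed by 1.28 and 1.34. Gas6 was above 0 in 9 dormant cells, all of them leukocyte-rich, and in 0 proliferating cells. Without leukocyte-rich cells it was therefore 0 in every cell and could not be tested, and Bhlhe41 differed by 1.39. Cell cycle inhibitors and quiescence genes had a median of 0.10 over 19 genes (adjusted p = 0.202), and p53 targets −0.58 over 17 (adjusted p = 0.952). Nuclear-encoded oxidative phosphorylation genes had a median of −0.13 over 50 genes (adjusted p = 0.717). Among mitochondrially encoded genes the median was 0.84, with 14 of 15 positive (adjusted p = 0.0018; adjusted p = 0.492 with an estimated correlation). It was −0.37 without mouse 288, where the call was lost (camera adjusted p = 0.666), and 1.29 without mouse 369. Without leukocyte-rich cells it was 0.67 and was not called (adjusted p = 0.664). Within the shared mice the median was −0.57, with 13 of 15 negative and no call (camera adjusted p = 0.555), and mt-Nd2, a complex I gene, was lower in 4 of 4 mice (−1.70, SE 0.63). Leaving out leukocyte-rich cells there gave −1.10, called lower (adjusted p = 5.58e-06).

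Stress and adhesion genes also had values apart. Immediate early genes had a median of 1.5, with 12 of 15 positive (adjusted p = 9.86e-05; adjusted p = 0.317 with an estimated correlation), and Fos, a stress-induced transcription factor gene, differed by 3.70 (SE 1.62). Fos was higher in 1 and lower in 3 of the 4 shared mice, and differed by 1.63 without low-label and 1.30 without leukocyte-rich cells. The list's median was 0.52 without mouse 360 and up to 2.01 without another mouse. Within the shared mice it was 0.61, and −0.55 without mouse 360, where the call was lost (camera adjusted p = 0.899), 0.40 without mouse 1185 and 1.71 without mouse 452. Leaving out low-label cells ended the call over all mice (0.79, camera adjusted p = 0.214) and turned the median within mice (−0.71, adjusted p = 0.290). Lysosome and autophagy genes had a median of 0.49 (0.78 without mouse 369, 0.85 without mouse 452), with Ctsd, a lysosomal protease gene, at 3.79 (SE 1.04; 2.24 without low-label cells; adjusted p of the list = 4.62e-05; adjusted p = 0.317 with an estimated correlation). The list was at 0.50 without low-label cells and not called (camera adjusted p = 0.0756). Within mice it went from 0.26 to −0.23 without low-label cells (adjusted p = 0.290), to −0.27 without mouse 360 and to −0.43 without leukocyte-rich cells, where it was called lower (adjusted p = 0.019). It was 0.44 without mouse 369 and 0.50 without mouse 452 there. Extracellular matrix genes had a median of −1.36 with 20 of 23 negative (adjusted p = 0.0454; adjusted p = 0.679 with an estimated correlation), and 0.17 without low-label cells. The call was lost without mouse 360 (−0.30, camera adjusted p = 0.527), mouse 244 (−0.99, adjusted p = 0.220) or mouse 452 (−1.37, adjusted p = 0.0503).

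The higher interferon response score in dormant cells may come from marrow leukocytes sorted with them. Without the low-label cells its score difference was 0.26 (SE 0.55), against 1.02 with all cells. That keeps 25.7% of it, under the bound of 0.51 set for this explanation, but the SE spans the bound, so the leukocyte source stays open rather than shown. This SE takes the means as unpaired. In the shared mice that remained, dormant and proliferating scores were 1.77 and 2.44 (mouse 1185), 2.98 and 3.15 (369), and 1.33 and 1.23 (452). In single cells the median score was 4.18 in low-label, 1.72 in labelled dormant and 1.65 in proliferating cells. Library batch and spike-in mix cannot be told apart from state, since 0 cells carried the mix of the other state, and a real interferon difference in labelled cells also stays open.

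The G2/M and mitosis median of −3.11 lay below that of lists matched on mean expression (−0.58), and 0% of 10000 were as low. A loss of detected genes that follows expression alone thus falls short of it. The 0% is no test of chance, since matched genes were not picked to vary together, while genes of this list do (estimated correlation 0.581 within mice). It was also 0% for G1/S and for ribosomal proteins. Without low-label cells the score difference was −1.70 (SE 1.60), against −3.03 with all cells and a bound of −1.52, so how far leukocytes contribute is undecided. This SE also takes the means as unpaired. Dormant and proliferating scores were 4.22 and 7.86 in mouse 1185, 8.34 and 7.49 in 369, and 2.11 and 5.38 in 452. In single cells the median score was 1.53 in low-label, 3.17 in labelled dormant and 7.47 in proliferating cells. The sort by dye dilution itself predicts such a difference, which stays a hypothesis, as batch follows state.

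Among labelled dormant cells 8 were leukocyte-rich, which may reflect reads shared between libraries, material of a pair of cells in one well, or uptake of leukocyte RNA, which was not tested. Their median Lyz2 was 1.01% of that in low-label cells, within the 5% allowed for shared reads. The highest was 56.5%, in mouse 1184, and 2 of 8 lay above 5%, so shared reads do not account for those cells. All 8 had eCFP and Krt8 within the range of other labelled cells, and 3 of them had Lyz2 and Ptprc above it, too few to decide for a pair of cells.

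For the count of 0 genes over all mice, 100 of 100 splits of the means gave as many, the highest other being 0. No split can give fewer than 0, so this share was fixed in advance and tested nothing. For the 23 lists over all mice, 4 of 100 splits gave as many, the highest other also 23. Among 48 splits that part the shared mice in the same way 3 did, the highest other 24. Of the shares for lists only the first, which leaves out the pairing, lay under 0.05, so chance is not excluded. Within mice 8 splits are too few for a share under 0.05. There the real counts were 0 genes, as in 8 of 8, and 21 lists, as in 2 of 8, with highest others of 0 and 21. The 8 of 8 was again fixed in advance by the count of 0.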
